A study of Mus musculus with 6 samples.

How the data were processed

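The study measured messenger RNA by bulk RNA-seq in crypt cells purified from the colon of C57BL/6 mice at 4 weeks of age. Per the labels, 3 libraries came from mice with both copies of M14 flanked by loxP sites (control 1 to 3), and 3 came from such mice that also carried Villin-Cre (mutant 1 to 3). Villin-Cre drives Cre recombinase in the gut epithelium, so that the flanked part of the gene is removed there. M14 is read here as Mettl14, which encodes the RNA-binding partner of Mettl3 in the complex that writes N6-methyladenosine (m6A) on RNA. Polyadenylated RNA was selected on oligo-dT beads and libraries were made with a stranded SMARTer kit, per the labels' protocols.

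The deposited files hold raw gene counts, 1 file per library. Reads were trimmed with Trim Galore 0.6.5 and aligned with STAR 2.6.1d to GRCm38, per the submitters' processing notes. Fragments were then counted per gene with featureCounts 1.6.4 against the GENCODE vM25 primary assembly annotation, per the file headers. The headers record paired fragments, counting on the strand of read 1, and no option to count reads with several alignments or reads lying on several genes. Near-identical genes can lose reads by this setting, so values of Gsdmc2, Gsdmc3 and Gsdmc4, of ribosomal protein genes and of some mitochondrially encoded genes (mt-Co2, mt-Co3 and mt-Atp6) are uncertain. The series design text speaks of 3 pairs of mice, but no label says which control goes with which mutant.

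Each file held 55487 genes in the same order, and every row named a gene. In total 43508 genes had a count in at least 1 library. Library totals ran from 24181631 to 35183636 counts. A count of 0 allows a level of up to 0.124 CPM (3 counts) in the shallowest library and 0.0853 CPM in the deepest. That floor covers counting error only, since reads made by PCR without molecular identifiers are not independent molecules. Pairs of libraries of 1 group differed by far more than counting noise, with a chi-square per gene of 14.2 to 94.5, so none was counted as a repeat of another.

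Counts were analysed in R 4.3.3 with edgeR 4.0.16, which the submitters' notes also name. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18539. Libraries were scaled by TMM, and CPM values below are TMM-scaled. The quasi-likelihood F test of edgeR compared genotypes, 2-sided, with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. Log2 fold changes are mutant minus control. Means are given with the SD over 3 libraries per group. A gene is said to have risen or fallen only where its adjusted p passed that threshold.

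The 40 gene lists and the rule for named genes were fixed before the data were examined. The rule always named Mettl14, the Gsdmc genes and Lgr5. It added the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups. Predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were left out there. From each list it took up to 4 tested members with the smallest p. Outside the rule, Gsdma, Gsdmd, Mettl3, Muc2, Reg4, Cdkn1a, Axin2, C1qa, Il1a, Ccl2, Cxcl1, Cxcl2 and Cxcl5 were chosen after their values were seen. Genes named only in the closing section come from lists described there, and were picked for mention after their values were seen. The lists held 790 places, all found in the files, of which 736 were tested.

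Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2). It asks whether the members of a list moved differently from all other genes. The correlation between genes was preset at 0.01, and p-values were adjusted over the 40 lists. Camera with a correlation estimated from the data, and fry, which asks whether a list's genes moved one way on balance, were alternatives. The other alternatives were 3 other scalings, 2 other filters on low counts, DESeq2 1.42.0, limma-voom with and without sample weights, and a test against a 1.5-fold change. A threshold of 0.01, a replicate block, removal of the most abundant genes, another prior count and leaving out each library were also tried. One alternative, without mutant 1 and mutant 2, was added after the values of sex-linked genes were seen.

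The fits were tested on simulated counts for 18493 genes, drawn from the real means, library sizes and spread, with 200 genes changed. For mutant against control, edgeR recovered 46.2% of genes changed by 1.5-fold, 58.2% of those changed by 2-fold and 93.9% of those changed by 4-fold, and 7.24% of its calls were false. In the real comparison far more than 200 genes passed the threshold, so these shares need not hold there. With 1 of the 40 lists changed, all 3 list tests called it. Camera with the preset correlation also called 2 other lists, and the other list tests called none. Simulated genes were drawn independently, so the list tests met no correlation between genes there. Transcript lengths, exons and GC content in the closing section came from GENCODE vM21, which is also on GRCm38. Figures were drawn with matplotlib 3.10.9.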

Results

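The series holds 6 libraries of polyadenylated RNA from purified colonic crypt cells of mice aged 4 weeks. It sets 3 control mice with flanked M14 alleles against 3 mutant mice that carried Villin-Cre as well. The control libraries held 34978529, 35183636 and 32165546 counts, and the mutant libraries held 26188638, 24181631 and 34842591. A row of ribosomal RNA, CT010467.1, took 7.76% to 8.90% of counts in controls, and 12.9%, 7.44% and 5.16% in mutant 1, 2 and 3. Correlations of log2 CPM lay between 0.988 and 0.989 among controls, between 0.985 and 0.989 among mutants, and between 0.940 and 0.952 across genotypes. The first principal component, with 73.5% of the variance, separated the genotypes. The study's title concerns methylation of GsdmC transcripts and the survival of Lgr5-positive stem cells. The comparison asks which transcripts differ between mutants and controls. Only mutants carried Villin-Cre, so effects of Cre itself cannot be told apart from those of losing Mettl14. These libraries do not measure m6A or protein.

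The targeted gene came first. Mettl14 (ENSMUSG00000028114.16, minus strand of chromosome 3, 123368297 to 123386108 on GRCm38) fell from 23.0 ± 2.78 CPM in controls to 12.8 ± 1.96 CPM in mutants (SD, n = 3 each). Single mutant libraries held 14.0, 13.9 and 10.5 CPM and single controls 26.2, 20.9 and 22.0 CPM, so the groups did not overlap. The log2 fold change was -0.85 (SE 0.13, adjusted p = 6.22e-04 by edgeR, and adjusted p = 0.0612 against a null of 1.5-fold). The labels do not give the flanked exons, and gene counts also take reads from the remaining exons and from cells without Cre.

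Transcripts of the Gsdmc family, pore-forming gasdermins clustered on the minus strand of chromosome 15, fell sharply. Gsdmc4 (63891264 to 63912297) fell from 208 ± 3.66 to 13.3 ± 3.33 CPM, and Gsdmc2 (63824346 to 63845177) from 195 ± 15.7 to 20.5 ± 1.604 CPM. Gsdmc3 (63857724 to 63878558) fell from 45.0 ± 6.56 to 10.4 ± 2.80 CPM. Their log2 fold changes were -3.97 (SE 0.15, adjusted p = 1.49e-07), -3.25 (SE 0.094, adjusted p = 3.25e-08) and -2.10 (SE 0.18, adjusted p = 1.84e-05). These genes are near-copies of one another, so the split of reads between them is uncertain. Gsdmc itself fell too (adjusted p = 0.00289) but lay near the detection floor, at 0.751 ± 0.297 CPM in controls and 0.0807 ± 0.0801 CPM in mutants. Its log2 fold change of -3.17 became -3.90 without mutant 2. The other tested gasdermins went the opposite way: Gsdme, Gsdma and Gsdmd rose, with log2 fold changes of 0.64, 1.53 and 0.70. Of the 7 tested members of the gasdermin list 3 rose and 4 fell, and camera from limma did not call the list (adjusted p = 0.201), whereas fry called it lower (adjusted p = 8.80e-04). With no filter on low counts, which brings in its other genes, the list's median turned from -2.10 to 0.61. The study's title names this family, so its fall in these samples is not independent evidence.

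**Figure D1:**
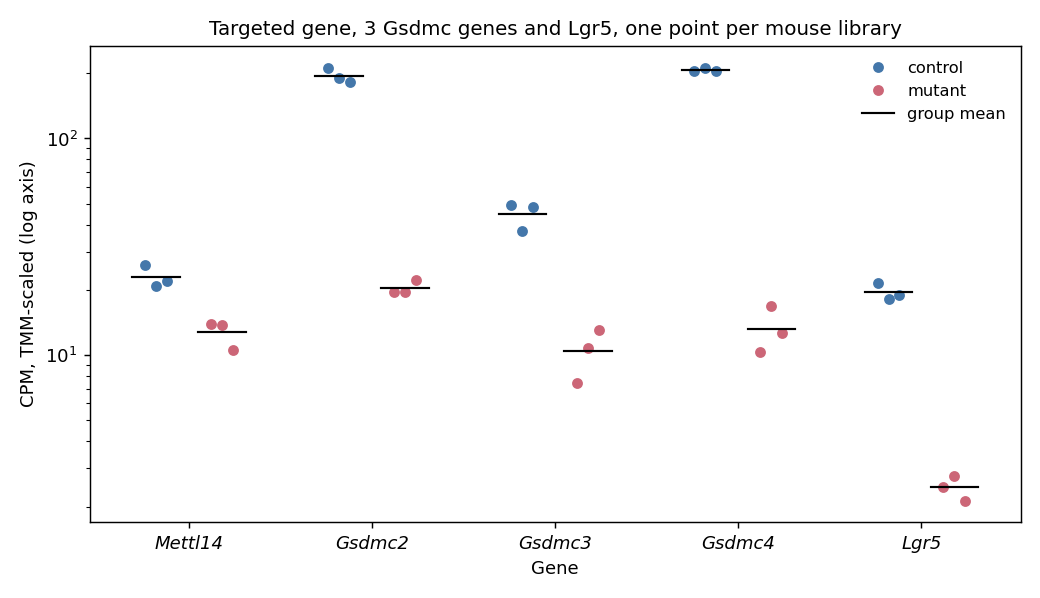
TMM-scaled CPM on a log axis for Mettl14, 3 Gsdmc genes and Lgr5, with 1 point per library and a line at each group mean (3 control and 3 mutant libraries). For each gene all mutant points lie below all control points, and the mean of Lgr5 is 19.6 CPM in controls and 2.46 CPM in mutants.

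Lgr5 (minus strand of chromosome 10, 115450311 to 115587780), the receptor that marks crypt-base columnar stem cells, fell from 19.6 ± 1.78 to 2.46 ± 0.315 CPM, a log2 fold change of -3.00 (SE 0.14, adjusted p = 4.17e-07). The stem cell list did not follow as a whole: of its 20 genes 5 rose, 7 fell and 8 did not pass. Rnf43, a Wnt receptor ligase, and Smoc2 fell, each with a log2 fold change of -0.90, whereas Ascl2, a transcription factor of the same stem cells, rose from 4.67 ± 0.608 to 10.04 ± 0.585 CPM. The list's median log2 fold change was 0.04, its mean was -0.07, and camera pointed down without a call (adjusted p = 0.787). Of 17 Wnt target genes 3 rose and 3 fell, and Axin2 stood at 48.6 ± 3.05 and 53.7 ± 1.54 CPM (adjusted p = 0.124). Apcdd1, a Wnt inhibitor, had the largest log2 fold change of that list (3.08), and camera did not call it (adjusted p = 0.893). Among 30 cell cycle genes 13 rose, 2 fell and 15 did not pass (camera adjusted p = 0.188). Birc5, Ccne1 and Cdk1 rose by 0.55, 0.72 and 0.34 on the log2 scale, while Kif11 fell by 0.27. Without mutant 1 and mutant 2 the log2 fold change of Cdk1 was 0.30 and its call was lost with the fewer libraries (adjusted p = 0.0515).

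Across the transcriptome, 8589 of 18539 tested genes passed the threshold (46.3%), with 4354 higher and 4235 lower in mutants. By more than 2-fold, 1952 were higher and 1122 lower. The CPM ranges of the groups did not overlap for 10542 genes (56.9%), where chance gives 10%. Against a null of 1.5-fold change instead of no change, edgeR called 1720 genes higher and 1027 lower.

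The largest rises were of transcripts almost absent from control crypts. Gabrp, a GABA-A receptor subunit, rose from 0.232 ± 0.0296 to 54.4 ± 1.49 CPM (log2 fold change 7.86, SE 0.12, adjusted p = 8.67e-10). Gp2, a glycoprotein of M cells that binds bacteria, rose from 0.0889 ± 0.0467 to 20.8 ± 4.63 CPM (7.79, SE 0.30, adjusted p = 1.37e-07). Ubd, a ubiquitin-like protein induced by inflammatory cytokines, reached 244 ± 71.7 CPM from 2.20 ± 0.389 CPM, and H2-M2, a non-classical MHC class I gene, reached 106 ± 1.45 CPM from 1.09 ± 0.360 CPM. Ncf4, a subunit of the phagocyte NADPH oxidase, rose from 0.671 ± 0.0453 to 69.7 ± 5.25 CPM. Kcnj15, Rptn, Ces1c, the transcription factor gene Sox8 and Akr1c21 completed the 10 largest, with log2 fold changes of 7.58, 7.10, 6.63, 6.55 and 6.50. For Rptn the value was 7.73 without control 2. Control levels of several of these genes rest on a few counts, so the sizes of their folds are imprecise.

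The largest falls were led by Gsdmc4 and included Gsdmc2. Slc37a2, a sugar phosphate transporter, fell from 422 ± 112 to 28.5 ± 9.90 CPM (log2 fold change -3.90, SE 0.29, adjusted p = 7.12e-06). Cps1, the first enzyme of the urea cycle, fell from 111 ± 37.2 to 8.86 ± 3.74 CPM, and Arg2, a mitochondrial arginase, fell from 15.8 ± 2.88 to 1.66 ± 0.459 CPM. Mptx1, a mucosal pentraxin, fell from 155 ± 46.9 to 14.0 ± 6.60 CPM, and Ang4, an antimicrobial ribonuclease, from 16.1 ± 0.953 to 1.78 ± 0.251 CPM. Sult1a1, Fndc5 and Gal3st2c had log2 fold changes of -3.25, -3.10 and -3.06, the last being -3.67 without mutant 1.

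Other parts of the m6A machinery mostly rose. Of 18 writers, erasers and readers other than Mettl14, 10 rose, 3 fell and 5 did not pass. The reader genes Ythdf2 and Ythdf1 rose from 49.4 ± 4.61 to 137 ± 8.46 CPM and from 34.3 ± 0.353 to 73.7 ± 6.56 CPM. Rbm15, a writer adaptor, rose by 1.13 and Mettl16, a separate methyltransferase, by 0.82 on the log2 scale. Mettl3, the catalytic partner of Mettl14, was among the 3 that fell, from 24.5 ± 0.509 to 16.8 ± 1.42 CPM. Camera called the list higher (adjusted p = 0.0198, and adjusted p = 0.644 with an estimated correlation). Without mutant 1 the adjusted p was 0.0517.

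Several genes of mature colonocytes were lower in mutants and others did not pass. Of 20 genes of absorptive colonocytes 10 fell, 1 rose and 9 did not pass. Adjusted over the list alone, 11 fell and 1 rose. Car1, a carbonic anhydrase, fell from 5613 ± 518 to 2076 ± 273 CPM, Mep1a, a brush border protease, from 316 ± 37.5 to 90.9 ± 22.7 CPM, and the phosphate transporter Slc20a1 from 296 ± 65.7 to 87.3 ± 18.0 CPM. Guca2b, which encodes the hormone uroguanylin, was the member that rose, from 8.70 ± 0.563 to 107 ± 24.5 CPM. Camera called the list lower (adjusted p = 0.0102, and adjusted p = 0.905 with an estimated correlation). The call was lost without mutant 1 (adjusted p = 0.0517) and with fry (adjusted p = 0.132). Of 10 genes of small intestinal enterocytes 2 rose and 5 fell (camera adjusted p = 0.188), with Apob down from 232 ± 10.2 to 76.4 ± 6.45 CPM and the bile acid carrier Fabp6 up from 2.05 ± 0.478 to 42.0 ± 17.4 CPM.

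Secretory lineages split within each list, and camera with the preset correlation called none of the lists of secretory cells. Called lower by fry were goblet cells (adjusted p = 1.13e-06), deep crypt secretory and Paneth cells (adjusted p = 0.00185) and tuft cells (adjusted p = 0.00185). Camera called the same 3 lower with no filter on low counts (adjusted p = 0.00144, 6.15e-04 and 6.15e-04). Of 18 goblet cell genes 5 rose, 10 fell and 3 did not pass, and 6 rose and 10 fell adjusted over the list alone (camera adjusted p = 0.187). Klk1 fell from 707 ± 86.5 to 199 ± 37.4 CPM, Spink4 from 999 ± 179 to 306 ± 46.7 CPM, and Muc2, the main secreted mucin, from 14080 ± 2842 to 6296 ± 896 CPM. Of 12 genes of deep crypt secretory and Paneth cells 2 rose and 5 fell (camera adjusted p = 0.114). Reg4, a marker of deep crypt secretory cells, fell from 999 ± 374 to 223 ± 95.2 CPM, Tgfa fell by 0.91 on the log2 scale, and the lysozyme gene Lyz1 rose from 1.37 ± 0.217 to 4.31 ± 0.700 CPM. In tuft cells 10 of 16 genes fell and 2 rose (camera adjusted p = 0.0886). Alox5 fell from 4.41 ± 0.483 to 0.639 ± 0.158 CPM and Rgs13 from 5.02 ± 0.297 to 1.24 ± 0.102 CPM, while the transcription factor gene Gfi1b rose from 0.238 ± 0.0657 to 3.54 ± 0.344 CPM. The tuft cell list was called lower without mutant 2 (adjusted p = 0.0358), as was the list of deep crypt secretory and Paneth cells (adjusted p = 0.0493). Enteroendocrine genes went both ways, with 7 of 18 up and 5 down. Their median was 0.00 and their mean -0.06, while camera pointed up without a call (adjusted p = 0.908). The hormone genes Nts and Gcg fell, by 2.52 and 1.38 on the log2 scale, and the transcription factor gene Neurod1 and the granin gene Scg2 rose, by 1.59 and 1.52. In the Notch pathway 4 of 10 genes rose and 2 fell, and 5 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.645). Atoh1, the factor that sets secretory fate, rose from 107 ± 7.79 to 185 ± 19.8 CPM, and Nrarp, a Notch feedback inhibitor, fell from 20.9 ± 2.03 to 8.52 ± 1.02 CPM.

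Nearly all NF-kB and inflammatory cytokine genes were higher. Of 16 tested members 14 rose, none fell and 2 did not pass, with a median log2 fold change of 2.48. Il1a, Il1b, Ccl2, Cxcl1, Cxcl2 and Cxcl5 were near the detection floor in controls, from 0.021 CPM (Ccl2) to 0.20 CPM (Cxcl5). The sizes of their folds, and with them the median, are imprecise. The chemokine gene Ccl20 rose from 0.989 ± 0.379 to 54.1 ± 9.60 CPM and Tnfaip2 from 0.675 ± 0.291 to 37.1 ± 6.33 CPM. Nfkb2, which encodes the p100 subunit, rose from 50.01 ± 2.94 to 211 ± 17.1 CPM, and Birc3, an inhibitor of apoptosis, from 54.1 ± 3.25 to 182 ± 15.3 CPM. Camera called the list higher (adjusted p = 6.25e-08, and adjusted p = 0.545 with an estimated correlation). Markers of macrophages and dendritic cells rose in the same libraries, 13 of 14 of them, with Lyz2 at 4.09 ± 0.388 CPM in controls and 18.4 ± 6.42 CPM in mutants.

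The genes of inflammation below were measured in libraries in which 13 of 14 macrophage and dendritic cell markers rose, among them Csf1r from 2.18 ± 0.110 to 9.99 ± 2.44 CPM and Itgax from 0.480 ± 0.0267 to 2.73 ± 0.712 CPM. Inflammasome and necroptosis genes divided evenly, 7 up and 7 down of 20. Nlrp6 and Casp1 fell, from 316 ± 10.7 to 133 ± 11.7 CPM and from 158 ± 13.3 to 86.9 ± 10.6 CPM. Il1b rose from 0.149 ± 0.143 to 7.95 ± 1.84 CPM, with a log2 fold change of 5.69 that became 6.60 without control 1. Nlrp3 rose from 0.0289 ± 0.0285 to 1.06 ± 0.346 CPM, with a log2 fold change of 4.97 that became 5.76 without control 1. Both genes lay near the detection floor in controls, so the sizes of their folds are imprecise. The median log2 fold change of this list was 0.08, its mean was 0.41, and camera pointed down without a call (adjusted p = 0.911). Among 32 interferon-stimulated genes 7 rose, 4 fell and 21 did not pass (camera adjusted p = 0.871). Oasl1 rose from 31.5 ± 4.01 to 106 ± 25.4 CPM, Mx1 and Rtp4 rose by 1.53 each on the log2 scale, and Ddx58 fell by 0.68. In antigen presentation 5 of 17 rose and 4 fell (camera adjusted p = 0.893). Cd74, the MHC class II invariant chain, rose from 12.3 ± 1.44 to 113 ± 17.2 CPM, while the class II chain gene H2-Aa rose from 1.66 ± 0.393 to 4.80 ± 1.25 CPM. Of 17 antimicrobial defence genes 4 rose and 6 fell, and 6 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.787). Dmbt1 fell from 8135 ± 1852 to 3968 ± 86.4 CPM and the nitric oxide synthase gene Nos2 rose from 9.49 ± 0.706 to 37.7 ± 20.7 CPM. The median and mean of that list were 0.01 and 0.05, whereas camera pointed down. Genes of the type 2 cytokine response included 2 that rose and 5 that fell of 10 (camera adjusted p = 0.584), with Il4ra, the interleukin 4 receptor, up by 1.48 and the goblet cell gene Clca1 down by 1.93 on the log2 scale.

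Regenerative and fetal-like genes rose in mutants, 12 of 17 tested, with 3 that fell. Sprr1a rose from 17.6 ± 3.92 to 192 ± 62.7 CPM, Il1rn from 20.4 ± 4.72 to 98.8 ± 23.0 CPM, the growth factor gene Areg from 27.7 ± 4.34 to 74.9 ± 3.28 CPM and Clu, a marker of revival stem cells, from 5.93 ± 0.265 to 37.1 ± 13.3 CPM. Camera called the list higher (adjusted p = 0.00635, and adjusted p = 0.821 with an estimated correlation).

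Targets of p53 also moved mostly upward, with 10 of 18 higher, 2 lower and 6 that did not pass. Gdf15, a stress-induced cytokine, rose from 1.75 ± 0.329 to 23.2 ± 1.13 CPM, and Phlda3 from 1.13 ± 0.544 to 12.7 ± 2.34 CPM. Aen rose by 0.75 on the log2 scale, whereas Trp53inp1 fell by 1.09. Cdkn1a, the p21 gene, stood at 107 ± 10.8 and 114 ± 13.1 CPM (adjusted p = 0.498). Camera called the list higher (adjusted p = 0.0464, and adjusted p = 0.545 with an estimated correlation). That call was lost without control 2 (adjusted p = 0.0664), without mutant 3 (adjusted p = 0.0833) and under the stricter low-count filter (adjusted p = 0.0509).

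Among 20 apoptosis regulators 4 rose and 7 fell, and 5 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.584). The survival genes Birc3 and Bcl2l1 rose, by 1.75 and 0.55 on the log2 scale, and Bcl2 fell from 23.7 ± 2.43 to 9.73 ± 2.29 CPM. The pro-apoptotic gene Bik rose from 1.88 ± 0.384 to 6.04 ± 1.48 CPM. In the unfolded protein and integrated stress response 10 of 21 genes rose and 7 fell, and 11 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.364, and 0.00617 with fry). Trib3 rose from 0.223 ± 0.0611 to 8.11 ± 1.13 CPM, Chac1 from 1.12 ± 0.234 to 13.0 ± 0.365 CPM, Asns, the asparagine synthetase, from 33.5 ± 4.49 to 86.2 ± 10.02 CPM, and the chaperone gene Hspa5 from 733 ± 37.9 to 1537 ± 155 CPM. Immediate-early genes, which respond to tissue dissociation, showed 7 of 19 higher and 1 lower (camera adjusted p = 0.143, and 0.0211 without mutant 1). Junb rose from 78.3 ± 4.86 to 192 ± 23.8 CPM and Hsph1 fell by 0.47 on the log2 scale.

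Fatty acid oxidation and PPAR target genes fell, 15 of 22 tested, with 1 that rose and 6 that did not pass. Cpt1a, the entry step of mitochondrial fatty acid oxidation, fell from 367 ± 19.1 to 222 ± 2.36 CPM. The receptor gene Ppara fell from 33.8 ± 4.12 to 13.3 ± 3.55 CPM. Camera called the list lower (adjusted p = 6.12e-04, and adjusted p = 0.545 with an estimated correlation). In the nuclear-encoded respiratory chain 30 of 79 genes fell, 5 rose and 44 did not pass, with a median log2 fold change of -0.20. Ndufs1, Ndufc1 and Uqcrc2 fell by 0.45, 0.50 and 0.47 on the log2 scale, whereas Ndufa4 rose from 50.1 ± 0.885 to 96.1 ± 1.31 CPM. Camera called this list lower (adjusted p = 0.00406, and adjusted p = 0.905 with an estimated correlation), and fry did not (adjusted p = 0.206). Of 11 mitochondrially encoded genes 4 rose and none fell (camera adjusted p = 0.367), led by mt-Nd1 and mt-Nd2 with log2 fold changes of 1.08 and 0.84. The calls of the other 2, mt-Nd3 and mt-Nd6, were both lost without control 1 (adjusted p = 0.055 and 0.0972) and without mutant 2 (adjusted p = 0.0522 and 0.0812), and that of mt-Nd6 also without control 2 (adjusted p = 0.0875) and without mutant 1 (adjusted p = 0.0688). In cholesterol biosynthesis 11 of 24 genes fell and 2 rose (camera adjusted p = 0.143, and 0.0319 without mutant 2). Cyp51 and the regulator Srebf2 fell by 0.44 and 0.45, and Fdft1 rose by 0.39 on the log2 scale.

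Cell junction genes went both ways, 7 up and 7 down of 19. Their median was -0.13 and their mean 0.10, and camera pointed down without a call (adjusted p = 0.871). Cldn4 rose from 84.8 ± 14.96 to 438 ± 97.7 CPM and Cldn15 fell from 129 ± 11.8 to 44.5 ± 6.02 CPM. Of 79 cytosolic ribosomal protein genes 8 rose, 2 fell and 69 did not pass, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.554). Rps4l rose from 20.04 ± 1.48 to 85.1 ± 4.86 CPM. Of 8 posterior Hox genes, which mark the colon, 2 fell and 6 did not pass (camera adjusted p = 0.143, and 0.0279 without mutant 2). Hoxd11 fell from 2.57 ± 0.344 to 1.22 ± 0.202 CPM, and the call of the other, Hoxd10, was lost without control 1 (adjusted p = 0.0565). For the other 31 of the 40 lists, those with no separate figure here, the counts adjusted over the list alone were the same as those over all genes.

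**Figure D2:**
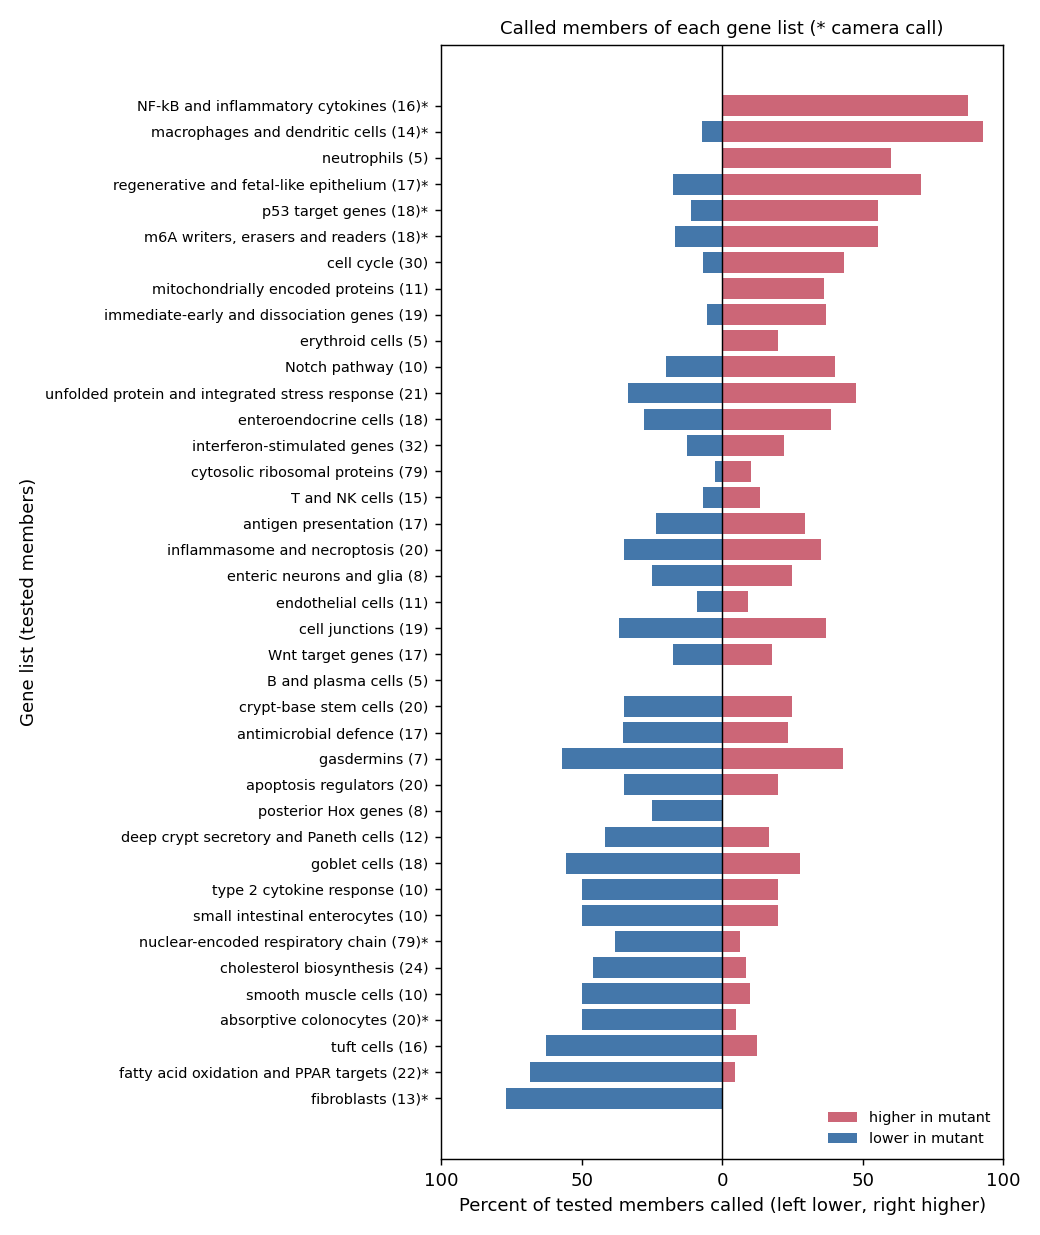
Percent of tested members of each gene list, the sex-linked list left out, that passed the threshold, higher in mutants to the right and lower to the left, with the number tested in brackets and a star at lists called by camera with the preset correlation. Of 16 NF-kB and inflammatory cytokine genes 14 were higher, and of 13 fibroblast genes 10 were lower.

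Markers of other cell types that a crypt preparation can hold moved in different directions. Of 13 fibroblast genes 10 fell, none rose and 3 did not pass. The collagen genes Col1a1 and Col3a1 fell from 51.0 ± 4.23 to 20.1 ± 1.87 CPM and from 111 ± 9.98 to 45.3 ± 6.61 CPM. Camera called fibroblasts lower (adjusted p = 3.74e-04, and adjusted p = 0.545 with an estimated correlation). Macrophage and dendritic cell markers were called higher (adjusted p = 2.88e-04, and adjusted p = 0.545 with an estimated correlation), with 13 of 14 up. Csf1r rose from 2.18 ± 0.110 to 9.99 ± 2.44 CPM and Itgam from 1.49 ± 0.468 to 5.39 ± 0.353 CPM. C1qa was the marker that fell, from 7.69 ± 3.13 to 2.88 ± 0.715 CPM. Of 5 neutrophil markers 3 rose, none above 2.19 ± 1.26 CPM in mutants (camera adjusted p = 0.143, and 0.0408 with fry). In the T and NK cell list 2 of 15 (Cd4 and Cd8b1) rose and 1 (Lck) fell (camera adjusted p = 0.656). None of the 5 tested B and plasma cell genes passed (camera adjusted p = 0.521). Without mutant 3, however, edgeR called Igkc and Igha higher (adjusted p = 0.00331 and 0.00266). Smooth muscle genes showed 1 of 10 up and 5 down, and 2 up and 5 down adjusted over the list alone (camera adjusted p = 0.271). The kinase gene Mylk was the one that rose, from 92.8 ± 4.78 to 348 ± 14.4 CPM. Of 11 endothelial genes Pecam1 rose and Emcn fell (camera adjusted p = 0.787), and the call of Emcn was lost without control 2 (adjusted p = 0.0865) and in 3 other fits with 1 library left out. Of 8 genes of enteric neurons and glia 2 rose and 2 (Snap25 and Uchl1) fell (camera adjusted p = 0.918), with the receptor gene Ret up from 4.23 ± 0.0982 to 19.4 ± 4.202 CPM. The calls of Snap25 and Uchl1 were lost without mutant 1 (adjusted p = 0.053 and 0.0808), among other libraries. Of 5 erythroid genes 1 (Alas2) rose, and none passed adjusted over the list alone (camera adjusted p = 0.337). The call of Alas2 was lost without mutant 2 (adjusted p = 0.179), among other libraries. Leaving out mutant 3 instead, edgeR called Hbb-bs, Hba-a1 and Hba-a2 higher (adjusted p = 0.00389, 0.0203 and 0.00956). Without mutant 1 and mutant 2, the calls of Cd4 and Cd8b1 were lost (adjusted p = 0.0693 and 0.0587), and the medians of the T and NK, B and plasma, and erythroid lists turned negative (-0.01, -0.29 and -0.32).

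The list calls had a limit of their own. All 5 higher and 4 lower lists lost their call with an estimated correlation between genes, where 3 lists had an unadjusted p under 0.05. For that reason the lists are described here by the counts of their members. Other splits of the 6 libraries called up to 14 lists. Each of those splits still held part of the genotype difference, so that number does not measure false calls. With no filter on low counts camera also called immediate-early genes and neutrophils higher (adjusted p = 0.0392 each), and cholesterol biosynthesis, smooth muscle, small intestinal enterocytes and posterior Hox genes lower (adjusted p = 0.00238, 0.0295, 0.0152 and 0.00423). Medians near 0 turned sign under some settings for the lists of stem cells, enteroendocrine cells, inflammasome, interferon-stimulated, antigen presentation, antimicrobial and ribosomal protein genes, and that of enteric neurons and glia did so under the stricter filter.

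The animals differed in sex-linked transcripts, and raised Xist was found only in mutants, so sex is partly confounded with genotype. Xist, the RNA of the inactive X chromosome, stood at 1.28, 1.31 and 1.77 CPM in control 1, 2 and 3, and at 652, 53.1 and 1.504 CPM in mutant 1, 2 and 3. The Y-linked gene Ddx3y stood at 53.6, 58.4 and 57.2 CPM in controls and at 0.541, 38.0 and 44.2 CPM in mutants. Of 5 sex-linked genes, 1 (Xist) passed the threshold, and its log2 fold change of 7.34 became 4.21 without mutant 1 and 0.02 without mutant 1 and mutant 2 (adjusted p = 0.97). The list's median was -1.02 and its mean 0.68, and camera pointed down without a call (adjusted p = 0.623). Without mutant 1, Ddx3y, Kdm5d and Uty fell (adjusted p = 0.00204, 5.50e-04 and 0.00571). Without mutant 1 and mutant 2 their log2 fold changes were -0.382, -0.506 and -0.408, so mutant 3 alone had less of Ddx3y, Kdm5d and Uty than the controls. Eif2s3y, the other Y-linked gene, stood at 67.5 CPM in mutant 3 and at 72.4, 80.6 and 68 CPM in control 1, 2 and 3. With mutant 1 and mutant 2 left out, a setting added after these values were seen, edgeR called 3353 genes higher and 3520 lower, and 6281 of these calls were shared with the full comparison.

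**Figure D3:**
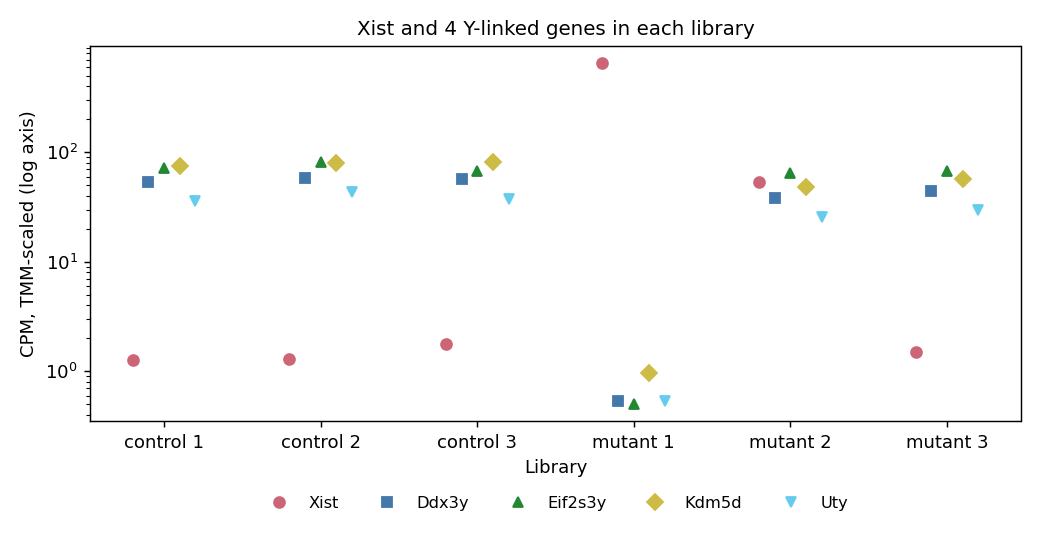
TMM-scaled CPM on a log axis of Xist and 4 Y-linked genes in each of the 6 libraries. Mutant 1 has Xist at 652 CPM with Ddx3y at 0.541 CPM, mutant 2 has Xist at 53.1 CPM with Ddx3y at 38.0 CPM, and the other libraries have Xist below 2 CPM.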

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

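The setting without mutant 1 and mutant 2 was chosen after the sex-linked values were seen; with 1 mutant library left, that library is assumed to vary like the controls. In the 19 gene alternatives, calls shared with the reported 8589 ran from 2747 (test against 1.5-fold) to 8565 (without the most abundant and mitochondrial genes). Mettl14 was lower in all 19, from -0.72 (without mutant 3) to -1.16 (without mutant 1 and mutant 2), and passed in all but the test against 1.5-fold, where its value was -0.854 (adjusted p = 0.0612). That test called 1720 genes higher and 1027 lower, since it asks for larger changes. Scaling by library size alone shifted the median log2 fold change from 0.006 to 0.078 and called 4881 genes higher and 3389 lower, so that 59% of calls were higher against 50.7% as reported.

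Camera called 0 lists higher and 0 lower with an estimated correlation, where fry called 7 and 6. It called 11 lists lower with no filter on low counts, 7 without mutant 1 and mutant 2, and 3 to 8 with 1 library left out (8 without mutant 2); the cause was not tested. With replicate numbers as a block, edgeR called 3789 genes higher and 3614 lower, Mettl14 stood at -0.854 (adjusted p = 9.61e-04), camera called 5 lists higher and 4 lower, and 6 other named genes lost their call. Deviations of same-numbered libraries correlated at -0.120, -0.065 and -0.138, so the numbers are not taken as pairs.

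The results that turned direction were not called as reported, and the cause was not tested. Without mutant 1 and mutant 2, log2 fold changes turned for Igkc (-0.146), Igha (-0.520), Ighm (-0.196), Hbb-bs (-0.321), Hba-a1 (-0.215) and Hba-a2 (-0.430). List medians turned there for stem cells (-0.081), interferon-stimulated genes (-0.053), antigen presentation (-0.092), antimicrobial defence (-0.033), ribosomal proteins (-0.013), T and NK cells (-0.010), B and plasma cells (-0.286) and erythroid cells (-0.321). With no filter on low counts they turned for gasdermins (0.609), enteroendocrine cells (-0.033), antigen presentation (-0.028) and antimicrobial defence (-0.026). The stricter filter turned antimicrobial defence (-0.062) and enteric neurons and glia (0.881), and upper-quartile scaling turned enteroendocrine cells (-0.011) and antigen presentation (-0.007). With 1 library left out, ranges were -0.140 to 0.378 for Ighm, -0.021 to 0.079 for stem cells, -0.069 to 0.094 for enteroendocrine cells, -0.061 to 0.212 for inflammasome genes, -0.215 to 0.167 for interferon-stimulated genes, -0.124 to 0.109 for antigen presentation, -0.141 to 0.219 for antimicrobial defence and -0.017 to 0.080 for ribosomal proteins. In the shallowest library a count of 0 allows up to 0.124 CPM, which limits genes near that level.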

Other observations

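The lists and tests on M cells and on the RANK pathway were drawn up after the rises of Gp2, Sox8 and Ccl20 had been seen, and the tests against lymphoid patch cells and against macrophages or dendritic cells were chosen after the values they measure were seen, as was the test of sex with no shared library. M cells are epithelial cells that carry particles from the gut lumen to lymphoid tissue. Of 25 genes associated with them 23 were tested, 21 rose, none fell and 2 did not pass. The values of 8 of these genes had been seen beforehand, and all 8 rose. They were Gp2, Sox8, Tnfaip2, Ccl20, Clu, Nfkb2, Relb and Scg5. Of the 15 other tested genes 13 rose. Spib, a transcription factor needed for M cell maturation, rose from 2.85 ± 0.0815 to 145 ± 9.60 CPM (log2 fold change 5.67, adjusted p = 8.67e-10). Msln, Tnfrsf11b, Mfge8 and Marcksl1 rose by 3.45, 3.36, 3.04 and 2.83 on the log2 scale, each higher in all 3 mutants. Ccl6 stood at 320 ± 64.4 and 267 ± 15.9 CPM (adjusted p = 0.141, and 0.00923 without control 1), and Prnp at 65.2 ± 5.59 and 60.4 ± 3.22 CPM (adjusted p = 0.288). Of the 23 genes, 18 had a control mean of at least 1 CPM, and 6 stood in another list as well.

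Most transcripts rose in a list built around the RANK receptor and non-canonical NF-kB pathway, which drives M cell differentiation. The list also holds Traf2 and Traf3, which restrain this pathway, and the canonical NF-kB genes Rela, Nfkb1 and Rel. Its counts therefore do not tell whether the pathway was more active. Of 10 tested genes of 11 named, 8 rose, 1 fell and 1 did not pass, with a median log2 fold change of 0.73. Tnfrsf11a, the RANK gene, rose from 85.4 ± 3.21 to 209 ± 30.7 CPM, and Map3k14, which encodes the NF-kB-inducing kinase, from 7.68 ± 0.694 to 22.1 ± 0.951 CPM. Traf3 and Traf6 rose by 0.94 and 1.08 on the log2 scale. Rel was the gene that fell, by 0.30, and its call was lost in each fit with 1 library left out (adjusted p = 0.128 without mutant 3).

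The split by genotype called 8589 genes, and the highest of the other 9 splits called 0 with edgeR (526 at an unadjusted p under 0.05) and 0 with limma-voom; 1 of the 10 splits called as many. For lists the split by genotype called 9, the highest other split called 14, and 9 of the 10 splits called as many. With 10 splits the share cannot fall under 0.1, so they are too few to tell. Each of the other 9 splits also put control and mutant libraries together in both groups. The genotype difference then added to the spread within groups, which by itself holds down gene calls. The 0 gene calls and the list calls of those splits therefore do not show what chance gives.

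The first pattern is the rise of M cell-associated genes. Of the 15 tested genes whose values had not been seen 13 rose, more than in 100% of 10000 random lists of the same size and mean CPM. That result goes with a wider M cell-associated programme in the mutant. The random lists drew genes independently, whereas genes of a single cell type can move together. The percentage is thus over genes and not over mice. Lymphoid patch cells would bring B cell transcripts, and the summed markers of B and plasma cells rose by 2.62 CPM against 20.7 CPM for Gp2, a ratio of 0.126 (SE 0.079). The marker sum was 6.92 and 9.72 CPM in mutant 1 and mutant 2, above the control range of 3.62 to 5.31 CPM. In mutant 3, with the most Gp2 (25.9 CPM), it was 4.32 CPM, within that range. The comparison rests on Gp2 alone and on markers near the floor, of which 5 of 11 passed the count filter. It therefore cannot tell whether lymphoid patch cells were present. Macrophages or dendritic cells carry several of these genes. Their 14 markers rose by 52.3 CPM in sum against 1622 CPM for the 21 M cell-associated genes that rose, a ratio of 0.0322 (SE 0.0058). Those 21 genes were summed because they rose, and the level of each in macrophages or dendritic cells was not measured. The ratio therefore cannot decide whether such cells were a source. Whether M cells became more frequent or other epithelial cells took up these genes also stays open.

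The second pattern is the spread of calls over 46.3% of tested genes, while 1 mutant had high Xist and almost no Y-linked transcripts and another had both. Of the 8589 called genes 100% had the same direction in mutant 3, without raised Xist, against the 3 controls, but mutant 3 and these controls had helped to choose them. With no library shared, genes called from mutant 1 and mutant 2 against 2 controls had the same direction in mutant 3 against the third control in 98.3%, 98.3% and 98.8% of cases, where no change gives 50%. That agreement in mutant 3 argues against the sex of the animals as the whole cause. Calls covered 43.1% of X-linked and 46.5% of autosomal genes. These 2 shares do not decide the question, since sex can also act on autosomal genes. A contribution to single genes stays open, and whether RNA of 2 animals was mixed in mutant 2 was not tested.

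The third pattern concerns exon structure, since m6A is depleted near splice junctions and lies mostly in long internal and last exons. Of 2774 genes with an internal exon of at least 400 nt 30.5% rose and 22.7% fell, against 25.2% and 27.4% of 11434 others. The difference of medians was 0.069, between the bounds of 0.05 and 0.1 set before the test, so whether loss of m6A contributes cannot be told apart from no effect of exon length. By library it was -0.045, 0.034 and 0.011 in control 1, 2 and 3 and 0.082, 0.036 and 0.063 in mutant 1, 2 and 3, so mutant 2 lay barely above control 2. Across genes the coefficient was 0.070 (SE 0.022) with transcript length, GC content and expression level and 0.040 (SE 0.021) without. It did not shrink when these were added. The difference of means without them was weak against its error, so what accounts for it cannot be decided. The errors are over genes and not over libraries, and the others were not sorted by the length of their last exon.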
